A study of Solanum lycopersicum with 2 samples.

How the data were processed

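Leaves of tomato (Solanum lycopersicum) cultivar Pusa Ruby were profiled by RNA sequencing after inoculation with the fungus Alternaria or after a mock inoculation. Per the labels' protocols, plants were grown at 25 °C and held in a humid chamber for 24 hours before inoculation. Infected leaves received droplets of about 10 microlitres holding about 1000000 colony forming units of Alternaria per ml, and mock leaves received the MES buffer. Leaves were collected about 72 hours after inoculation, and from infected plants only the infection zone was taken. Poly(A) RNA from 1 microgram of total RNA was fragmented, copied from random hexamers and amplified with 11 PCR cycles following an Illumina TruSeq RNA protocol that, as described in the labels, includes no step that marks strand.

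The deposited values are raw read counts per gene, per the file headers, with 1 library for each of the 2 conditions. They are whole numbers with different totals and carry no normalization. TopHat2 2.0.7, Cufflinks 2.0.1 and Cuffdiff are named in the submitters' processing notes, with no role or order. The tool that counted reads, its settings for strand and for reads that match several genes, the genome build and the annotation release are not given in the sources used here. Both libraries list the same 23523 gene identifiers of the form Solyc, and every row carries such an identifier. Values for genes that were near-identical copies, overlapped or lay antisense to each other are therefore uncertain, since how their reads were divided is not known.

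The identifiers come without gene names. None could be matched (0 identifiers) in a RefSeq table of 41476 tomato genes on assembly SLM_r2.1, which holds no identifiers of this form. Genes are therefore reported by identifier, and no function is assigned. The 47 gene lists fixed before the data were examined (defence proteins, hormone and phenylpropanoid synthesis, photosynthesis, stress, markers of other leaf cell types and others) select genes by product name, so they were not run. For the same reason, the rule for named genes had no eligible member where it asked for the 12 most different genes per direction with a product name or for members of a list. Its last part asked for the 5 most abundant genes per library. These are described as a group, and the gene ranked first in both is named. In place of the other parts, the 2 identifiers with the highest and the 2 with the lowest log2 ratio among genes at 10 CPM or more in at least one library are given. That reduced rule was set after the data had been opened.

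Values had been planned for as FPKM, with CPM as the fallback for count files, and the fallback was used. Counts were scaled to CPM, the counts a gene would have in a library of 1000000 counts. The log2 ratio is log2((infected CPM + 1)/(mock CPM + 1)), which understates the difference of low genes. Genes at 1 CPM or more in at least one library were compared, and a ratio of 2 or more in size counted as a difference. With 1 library per condition no test between conditions is possible, no p-value is given, and the count of genes past a size is a description of these 2 libraries. Ratios of counts carry 95% exact intervals (Clopper-Pearson, from the split of the summed count), computed without the pseudocount. Sequencing reads are not independent molecules, so these intervals, and the limit of 3 counts used where a library had 0, cover counting error only. The totals of 63370555 and 64554299 counts put 1 CPM at 63.4 counts in the mock library and 64.6 in the infected library.

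By the naming convention of these identifiers, the first digits give the chromosome (0 for unplaced sequence) and the last digits the order along it, usually in steps of 10. Chromosome medians and shares were set against 10000 shuffles of the log2 ratios among genes of similar mean expression (20 bins). A run was defined, after the data had been opened, as at least 4 genes next to each other in identifier order, among the genes compared, that all differed at least 4-fold in the same direction. Runs were counted again in the same shuffles. Correlations between neighbours used 1000 of the shuffles. No coordinates are given, because the build of the annotation is not known.

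Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The calcNormFactors function of edgeR 4.0.16 in R 4.3.3 gave trimmed mean of M-values (TMM) factors, used as a scaling alternative only. The code was tested on simulated data drawn from the mock library. Of 200 genes changed 4-fold, the 2-fold rule recovered 89% with counting error alone, 91% with an assumed 20% variation between libraries and 77% with 40%. Of 200 genes changed exactly 2-fold, at the threshold itself, it recovered 17%, 39% and 44%. The added 1 CPM shrinks the ratio, but its part in these values was not isolated. Of the unchanged genes in the 4-fold simulations, 0 of 18857 passed 2-fold with counting error alone, 183 of 18968 with 20% variation and 3513 of 19055 with 40%. Alternatives were other pseudocounts (0.1 and 5 CPM), other scalings (median, upper quartile, TMM), other filters (none and 5 CPM) and a 4-fold threshold. Further alternatives for the runs, and totals without the 100 most abundant genes, were added after the data had been opened.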

Results

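Gene expression was measured in leaves of the tomato cultivar Pusa Ruby about 72 hours after inoculation with Alternaria, a genus of fungi that includes agents of leaf blight, and in leaves inoculated with buffer. The mock leaf was described as normal and the infected leaf as chlorotic or slightly blighted. There was 1 library per condition, so no value below has a replicate and no difference has a replicate check. The mock library held 63370555 counts and the infected library 64554299. Of the 23523 genes listed, 23010 had at least 1 count in the mock library and 22996 in the infected library, 22486 had counts in both, and 3 were at 0 in both. The 1261 most abundant genes held 50% of the mock counts, against 1191 genes in the infected library.

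The comparison of infected with mock leaf asked which genes of the tomato transcriptome respond to Alternaria. At 72 hours, 19932 genes stood at 1 CPM or more in at least one library. Of these, 2840 (14.2%) were at least 2-fold higher in the infected library, 4537 (22.8%) were at least 2-fold lower, and 12555 lay within 2-fold. The genes at least 2-fold higher took 37.7% of the infected counts and 6.95% of the mock counts. The genes at least 2-fold lower took 8.25% of the infected counts and 35.0% of the mock counts. Across genes, log2(CPM + 1) in the infected library correlated with that in the mock library at r = 0.75 (Spearman rho = 0.77); genes are not independent replicates.

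The balance of directions depended on the size of the difference. At 4-fold, 1431 genes were higher and 1353 lower. At 16-fold, 355 genes were higher and 143 lower, and at 64-fold 73 were higher and 23 lower. The 355 genes at least 16-fold higher went from 0.171% of the mock counts to 9.01% of the infected counts, and the 143 genes at least 16-fold lower went from 6.51% to 0.16%. At the 2-fold threshold, the 95% exact interval for counting error lay wholly beyond 2-fold for 2760 of the 2840 higher and 4374 of the 4537 lower genes. Genes were chosen with 1 CPM added and the intervals computed without it, which helps low genes to lie beyond the threshold. Variation between plants was not measured, and in simulated libraries with an assumed variation of 40% between libraries 3513 of 19055 unchanged genes passed 2-fold. The median gene stood at a log2 ratio of -0.28 in the infected library. TMM scaling brought that median to -0.01 and turned the 2-fold split from 38.5% higher to 50.9% higher (3528 higher, 3405 lower). The 16-fold split became 423 higher and 115 lower, since raising the ratios can only add to the higher genes. The 16-fold counts moved with the pseudocount, to 662 higher and 429 lower with 0.1 CPM and to 156 higher and 62 lower with 5 CPM.

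**Figure D1:**
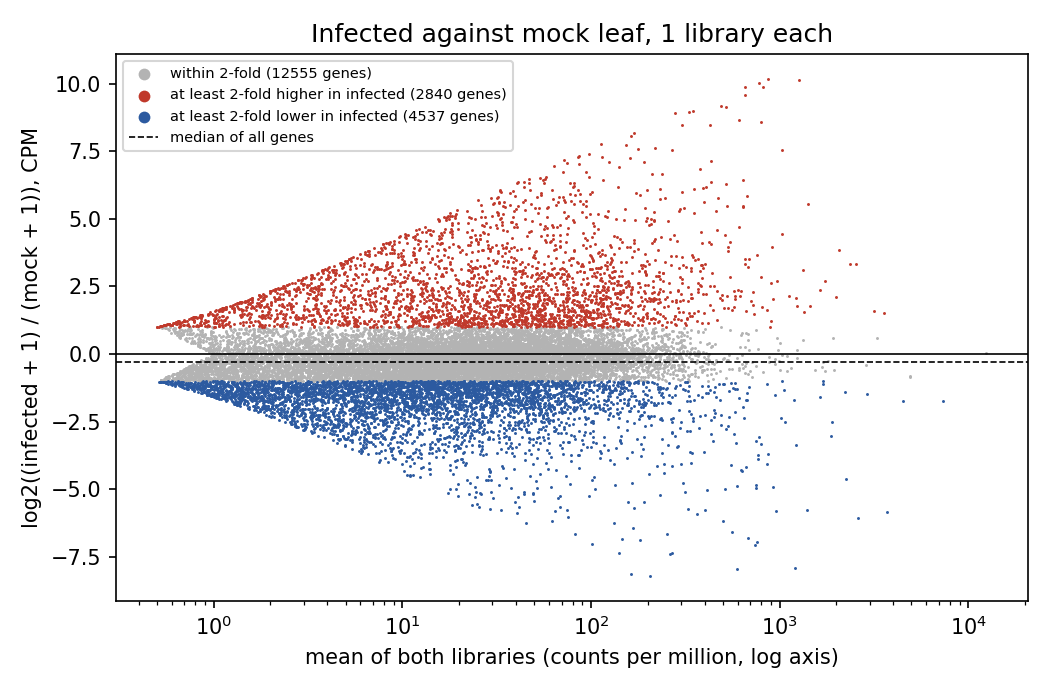
Log2 ratio of infected over mock CPM, each with 1 CPM added, against the mean CPM of both libraries on a log axis, with 1 point per gene for 19932 genes. Of the genes past 2-fold, 2840 lie above 0 and 4537 below it, the largest ratios reach above 10, and the dashed line marks the median of -0.28.

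The direction also differed with expression level. Genes were divided by mean CPM into 10 classes of equal size. In the highest class, above 108 CPM, 25.7% were at least 2-fold higher in the infected library and 18.3% at least 2-fold lower. In the class from 3.83 to 7.21 CPM, 11.8% were higher and 30.4% lower. The median log2 ratio was -0.51 in that class and 0.01 in the highest. The level of each class median depends on the scaling, and no other scaling was run by class. The added 1 CPM also shrinks ratios most in the low classes, so the 2-fold shares are not strictly comparable across classes.

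The most abundant genes differed between the libraries. The 100 most abundant genes of the mock library held 19.4% of its counts and 8.80% of the infected counts, and 65 of them were at least 2-fold lower in the infected library, 33 within 2-fold and 2 higher. The 100 most abundant genes of the infected library held 17.6% of its counts and 10.4% of the mock counts, and 70 of them were at least 2-fold higher and 6 lower. The lists shared 30 genes. Ranking by 1 library favours genes that are high in it, so part of each imbalance comes from the ranking. The gene ranked first in both libraries was Solyc12g094620 on chromosome 12, with 12301 CPM in the mock and 12578 CPM in the infected library, a ratio of 1.02 (95% exact interval 1.02 to 1.03). Its log2 ratio was 0.03, and 0.35 under TMM scaling. Of the 5 most abundant genes of the mock library, 3 were at least 2-fold lower in the infected library, while 4 of the 5 most abundant genes of the infected library were at least 2-fold higher there.

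By log2 ratio with 1 CPM added, the 2 highest and the 2 lowest genes all lay on chromosome 2. A gene in a run on chromosome 3 came close to the highest, at a log2 ratio of 10.03. The order of such near values depends on the added CPM, and genes were not ranked again without it. The shared chromosome therefore holds for this ranking only. Folds given below are without the added CPM. Solyc02g078650 had 32 counts (0.505 CPM) in the mock library and 112165 (1738 CPM) in the infected library, a log2 ratio of 10.17 and a 3441-fold higher level (95% exact interval 2437 to 5031). Solyc02g070110 went from 78 counts (1.23 CPM) to 163283 (2529 CPM), a log2 ratio of 10.15 and a 2055-fold higher level (interval 1646 to 2599.9). Solyc02g070970 had 26042 counts (411 CPM) in the mock library and 25 (0.387 CPM) in the infected library, a log2 ratio of -8.21 and a 1061-fold lower level (interval 719 to 1640.0). Solyc02g071000 had 20585 counts (325 CPM) and 10 (0.155 CPM), a log2 ratio of -8.14 and a 2097-fold lower level (interval 1140.0 to 4374).

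Some genes had counts in 1 library alone. There were 510 genes at 0 in the mock library with counts in the infected library, and 524 genes the other way round. Most were low, with medians of 13.5 and 11 counts in the library that had them. Set against the limit of 3 counts in the empty library, 172 genes were at least 10-fold higher in the infected library and 139 at least 10-fold lower. That bound takes the count in the other library as exact. Only 122 of the 510 genes and 63 of the 524 reached 1 CPM. Some genes past the bound thus lay below the level used for the genes compared. The extremes were a gene with 9246 infected counts, at least 3026-fold higher (143 CPM), and a gene with 2971 mock counts, at least 1009-fold lower (46.9 CPM).

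Whole chromosomes differed little. Chromosome medians of the log2 ratio ranged from -0.34 in unplaced sequence to -0.24 on chromosome 8, and each of the 13 medians lay within the central 95% of its 10000 expression-matched shuffles. The share of genes at least 2-fold higher ranged from 11.8% on chromosome 11 to 16.02% on chromosome 8, with 15.98% on chromosome 2. Chromosome 11 stood at percentile 1.67 of its shuffles, chromosome 2 at percentile 99.3 and chromosome 8 at percentile 96.5. These were picked from 13 values. The shuffles also ignore that neighbouring genes resembled each other, so they may overstate how far a chromosome stood apart. Chromosome 8 held 6.61% of all counts in the mock and 8.15% in the infected library, and chromosome 2 held 10.6% and 9.71%.

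Within chromosomes, some of the genes that differed strongly stood next to each other in identifier order. There were 20 runs of at least 4 neighbouring genes that all differed at least 4-fold in the same direction, 15 higher and 5 lower in the infected library, on 9 chromosomes. They held 100 (3.59%) of the 2784 genes that differed at least 4-fold. The 72 genes in higher runs went from 0.104% of the mock counts to 2.14% of the infected counts. The 28 genes in lower runs went from 1.06% to 0.0129%. Shuffles of the ratios among genes of similar expression gave 0.911 runs on average and at most 7 in 10000 shuffles. The number of runs depended on the pseudocount, with 44 at 0.1 CPM and 8 at 5 CPM, for which no shuffles were made. Neighbours that are near-identical copies may share reads, so values of single members are uncertain.

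The longest of these runs was on chromosome 2 and held 9 genes, among them Solyc02g070970 and Solyc02g071000. Its summed counts were 426284 in the mock library (0.673% of the total) and 1785 in the infected library (0.00277%), a 243-fold lower level (95% exact interval 232 to 255), and the members' log2 ratios ran from -8.21 to -3.59. On chromosome 7, a run of 7 genes went from 182072 to 3631 counts, a 51.1-fold lower level (interval 49.4 to 52.8). There, 1 gene held 65.6% of the mock level, and the members' log2 ratios ran from -6.67 to -3.07. Folds of summed counts follow the most abundant members of a run. A further run of 4 genes on chromosome 2 went from 28758 to 157 counts, a 187-fold lower level (interval 160 to 219.7).

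Higher runs included 2 close together on chromosome 8, of 8 and 6 genes. The first went from 15269 to 314385 counts, a 20.2-fold higher level (95% exact interval 19.9 to 20.5), and the second from 7074 to 166465 counts, a 23.1-fold higher level (interval 22.6 to 23.7). At a 2-fold threshold they joined through 1 gene with a log2 ratio of 1.41 into a run of 15 genes with a median log2 ratio of 4.39. That run went from 0.0505% of the mock counts to 0.786% of the infected counts. On chromosome 1, a run of 6 genes was 27.5-fold higher (interval 26.1 to 29.1). On chromosome 3, a run of 5 genes was 68.9-fold higher (interval 66.2 to 71.7). In it, 1 gene held 46.0% of the infected level, and the members' log2 ratios ran from 2.84 to 9.14. Also on chromosome 3, a run of 4 genes went from 47 to 123965 summed counts. In that run of 4, 1 gene held 81.3% of the infected level, and the members' log2 ratios ran from 3.44 to 10.03 with a median of 5.94.

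**Figure D2:**
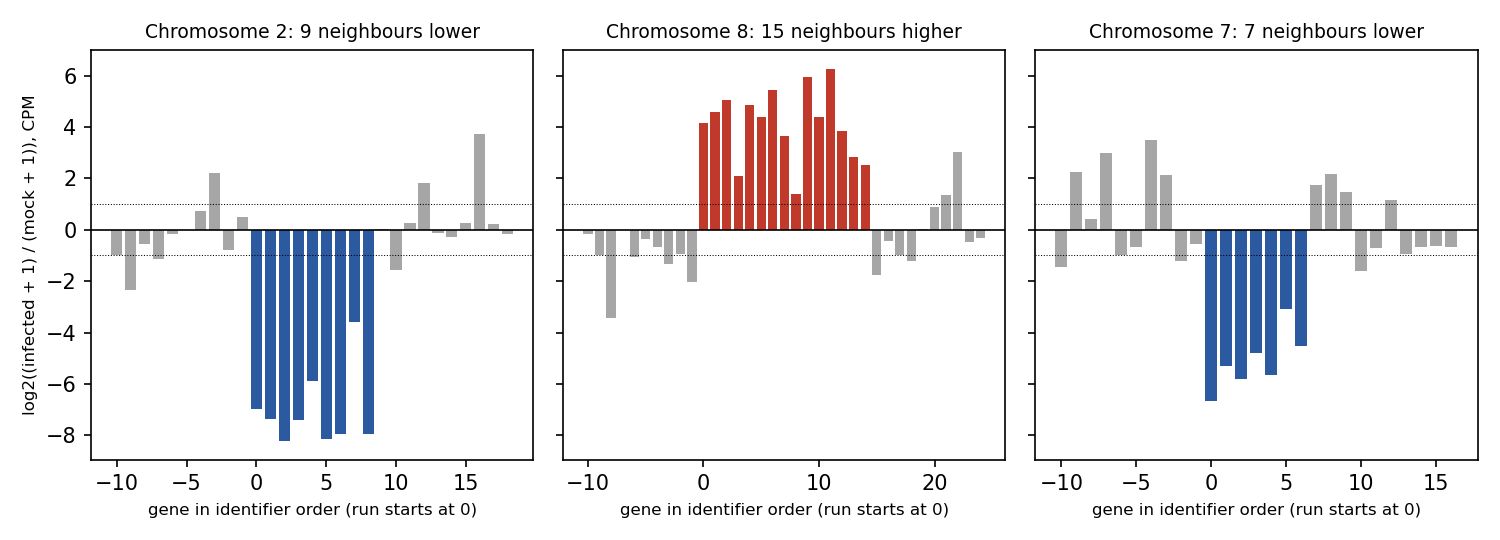
Log2 ratio of infected over mock CPM, each with 1 CPM added, for single genes in identifier order in 3 stretches, each with up to 10 genes on either side in grey; dotted lines mark 2-fold. Blue bars are the 9 lower genes on chromosome 2 and the 7 lower genes on chromosome 7, and red bars the 15 higher genes on chromosome 8, with log2 ratios from 1.41 to 6.27.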

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

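All results rest on 1 library per condition. No paired analysis was possible because each condition has 1 library, and for the same reason no replicate could be left out. The gene list medians and their alternatives were not run, because the identifiers could not be tied to product names. Of the counts of genes at least 2-fold higher or lower, the 4-fold threshold, as its construction requires, reduced both (1431 higher, 1353 lower), and a pseudocount of 5 CPM reduced the lower genes to 2641, since it compresses the ratios of low genes. Under the other pseudocount, scaling and filter alternatives (for the higher genes also with 5 CPM added) and under totals without the 100 most abundant genes, the higher count ranged from 2142 to 3528 and the lower count from 3405 to 5483, all within 1.5 times 2840 and 4537. More genes lay above 2-fold than below it under TMM scaling and also when ratios were taken relative to the median gene (3561 higher, 3249 lower). Under median, upper quartile and TMM scaling, under the filters tried and with identifier numbers at most 50 apart, there were 19 to 23 runs of neighbours. Totals without the 100 most abundant genes were not tried for the number of runs. It was 130 at a 2-fold threshold, 64 with runs of at least 3 genes, 44 with a pseudocount of 0.1 CPM and 8 with a pseudocount of 5 CPM. These alternatives for the runs were chosen after the data had been seen. The 4 genes with extreme ratios kept their direction but moved with the pseudocount (0.1 and 5 CPM): Solyc02g078650 to 11.49 and 8.31, Solyc02g070110 to 10.89 and 8.67, Solyc02g070970 to -9.72 and -6.27, and Solyc02g071000 to -10.32 and -6.00 on the log2 scale. The ratio of Solyc12g094620 was near 1, and its log2 value turned to -0.0072 when the 100 most abundant genes were left out of the totals. At 16-fold, the counts moved by over 1.5 times with the pseudocount, to 662 higher and 429 lower at 0.1 CPM and to 156 higher and 62 lower at 5 CPM. At this depth 1 CPM is 63.4 counts in the mock and 64.6 in the infected library. With counts halved, as a guard against reads counted in pairs, the 95% exact interval still lay beyond 2-fold for 2717 higher and 4166 lower genes.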

Other observations

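The tests in this part were chosen after the values they concern had been seen. Neighbouring genes resembled each other, less so at a greater distance. Across genes, the log2 ratios of direct neighbours in identifier order correlated at r = 0.165, of genes 2 steps apart at 0.0848 and of genes 3 steps apart at 0.0218. The highest values in 1000 expression-matched shuffles were 0.02115 for direct neighbours, 0.02696 at 2 steps and 0.02115 at 3 steps. The value at 3 steps thus lay only just above its shuffles. At 5 steps the correlation was 0.0136, and 26 of 1000 shuffles gave as much. At 10 steps it was 0.00347, and 344 of 1000 shuffles gave as much. Of the 20 genes with the largest lower ratio, 10 stood in a run of at least 4 neighbours, and of the 20 with the largest higher ratio 4 did. Among all genes at least 4-fold different, 28 of 1353 lower and 72 of 1431 higher genes stood in such runs. Members of the same run are not separate instances. At 2-fold there were 130 runs, 51 higher and 79 lower, against 48.8 on average in the shuffles.

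Similar mean expression of neighbours, as held by the 20 bins, does not account for the 20 runs at 4-fold. Of 10000 shuffles within these bins, 0 gave as many. The bins use the mean of both libraries, so a level that neighbours share in 1 library alone was not held fixed. Runs made wholly of identical copies with their reads divided between them would show 1 shared ratio, but the median range of log2 ratios within a run was 2.75. A run that mixes such copies with other genes would also show a wide range. The added 1 CPM further spreads the ratios of members at different levels. The range therefore does not exclude identical copies among the members of a run. Copies that share part of their reads cannot be told apart from neighbours that respond separately, because 0 identifiers could be tied to a sequence. Tandem gene families whose members respond alike are a candidate explanation that the data here leave untested.

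Over the scalings, the higher share at 16-fold ranged from 70.4% to 78.6%. The lowest share came with the 100 most abundant genes left out of the totals and the highest under TMM. Median, upper quartile and TMM scaling raised the ratios, which can only add to the higher share. Leaving out the 100 most abundant genes lowered the median log2 ratio only from -0.28 to -0.32. These scalings therefore cannot decide whether scaling sets the excess of large differences in the higher direction. A pseudocount of 0.1 CPM moved the higher share at 16-fold more, to 60.7% (662 higher, 429 lower). With 5 CPM it was 71.6% (156 higher, 62 lower), near the 71.3% with 1 CPM. An effect of low counts and the pseudocount on the size of the excess therefore stays open. The share of 71.6% among 2963 genes at 100 CPM or more in one library (187 higher, 74 lower) does not decide it, because a 16-fold gene passes that level through its higher library alone. These shares could still differ in other plants, since the libraries are single. Infection is confounded with sampling, because only the infection zone was taken from infected leaves, so tissue choice and response to the fungus remain open as untested explanations.

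Low counts were even more often than odd. Among genes with 1 to 10 counts, 53.9% of 1411 values in the mock library were even (95% exact interval 51.3% to 56.6%), and 57.6% of 1873 in the infected library (55.3% to 59.8%). Both intervals lay above 50%, the lower bound in the mock library being 51.29%, which argues against counting chance in this range. The excess stopped there: from 11 to 50 and from 51 to 1000 counts the intervals held 50% in both libraries, and above 1000 and up to 10000 counts the mock share was 48.7% (47.7% to 49.7%), an interval that misses 50% the other way. Of the 10 even counts from 2 to 10 in both libraries, 9 were held by more genes than the mean of their odd neighbours, but this counts the same genes again and decides nothing. Whether some reads were counted in pairs, as both mates of a fragment or as duplicates, stays open. If so, the intervals given for counts would be too narrow. With counts halved, the interval for Solyc02g071000 widened from 1140.0 to 4374-fold lower to 898 to 6459-fold lower.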
